A study of Mus musculus with 4 samples.

How the data were processed

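RNA from mouse sciatic nerve was measured on Illumina MouseWG-6 beadchips, in 4 arrays that each carried a pool of 3 nerves dissected from 3 different mice. There were 2 pools of control nerves and 2 pools of LKB1-SCKO nerves, 6 mice per genotype, all at postnatal day 60 and of a mixed FVB and C57BL/6 background. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, and amplified into biotin-labelled cRNA. Because every nerve came from a different mouse, the spread between pools of a genotype holds both biological and technical variation, and with 2 pools per genotype the number of arrays limits the precision.

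The deposited table of unprocessed values gives, per the file headers, a non-normalized signal intensity for each of 45281 probes and a detection p-value beside it. These intensities are on a linear scale, all above 0, with medians of 153, 157, 154 and 167 for control 1, control 2, LKB1-SCKO 1 and LKB1-SCKO 2. The detection p-value, per the file headers, has steps that correspond to 936 negative controls per array. A further deposited table holds the authors' processed intensity values, on a linear scale, with the same distribution on all 4 arrays, a minimum of -53.1 and a median of 13.6 on each array. Within each array the processed values kept the rank order of the unprocessed ones, which is what background subtraction followed by quantile normalization would leave. The steps themselves are not given in the sources used here. GenomeStudio (2010) is named in the submitters' processing notes, and neither a genome build nor a slide is given in the sources used here, so no coordinates are printed and slide could not be used as a block.

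Probe names came from the platform annotation. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. Symbols were updated through the gene identifiers of a RefSeq table (assembly GRCm38.p6), where 34807 probes matched and 78 did not and kept the platform's symbol. Names of near-identical gene families, such as globins, glutathione transferases, major urinary proteins and histones, are uncertain because a probe can bind several members.

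Starting from the unprocessed intensities, background was corrected by the normexp model of limma 3.58.1 (R 4.3.3), with the negative control mean and spread inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. A probe was kept when its detection p-value was under 0.05 on both arrays of at least 1 genotype, which left 19732 probes, 16821 of them with a gene. For the 4115 genes with several kept probes, the probe with the highest mean log2 value stood for the gene, which gave 10858 genes. Genotypes were compared with lmFit and eBayes of limma, two-sided, with genotype as the only term and Benjamini-Hochberg adjustment over the 10858 genes at 0.05. The prior had 3.29 degrees of freedom beside 2 residual ones. All fold changes are LKB1-SCKO over control. Where a gene was undetected on both arrays of a genotype, only a bound is given, written as at least N-fold. It compares the mean of the brighter genotype with the mean, over the arrays of the dimmer one, of the higher of the lowest detected signal and the probe's own signal. Such a bound holds for this processing only.

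The fixed gene lists were written before the data were examined and tested with camera of limma, using a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists with at least 5 measured members. Camera with an estimated correlation and fry were the alternatives. Of the 33 lists, 6 covered Schwann cells and lipid or sugar metabolism: myelin, immature or repair Schwann cells, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, and glycolysis with lactate transport. Another 11 covered oxidative phosphorylation, the citrate cycle, ATF4 targets, the unfolded protein response, NRF2 targets, LKB1 partners with AMPK and related kinases, CREB and CRTC targets, HIF1 targets, the circadian clock, proliferation and ribosomal proteins. The remaining 16 were markers of other cells and of sex: macrophages, lymphocytes, MHC class II, interferon response, chemokines and cytokines, mast cells, adipocytes, skeletal muscle, fibroblasts, perineurium, basal lamina, endothelium, mural cells, red blood cells, neurons and sex-linked genes.

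Named genes followed a rule that was also set before the data were examined. It took Stk11, then the 12 largest rises and 12 largest falls among genes past the threshold whose pools did not overlap, leaving out unnamed clones. From each list it took up to 4 members past the threshold by size of change, or the 2 brightest members if none passed, and all measured clock and sex-linked genes. A gene named beyond this rule is said to have been chosen after its values were seen.

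The fit was tested on simulated data with the 10858 genes and the spread of the real arrays, in 20 simulations with 200 changed genes each. It recovered 0.3% of genes changed 1.5-fold, 24.6% at 2-fold, 91.4% at 4-fold and 97.6% at 8-fold, and 4.66% of its calls were false. In the same simulations, a list of 20 genes shifted by 0.5 on the log2 scale reached an unadjusted p under 0.05 in 100% of runs with the preset correlation and 95% with an estimated one, and an unshifted list in 5% with the preset. Simulated genes were drawn independently of each other, without the differences in muscle, sex-linked and blood transcripts seen between the real pools. The share of false calls and the recovery hold for that setting and are not those of the real comparison. Estimated correlations within real lists reached 0.66 for macrophages and 0.86 for adipocytes, so the rates for lists do not carry over to such lists. Alternatives set before the data were examined were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter on dim probes, a stricter filter, an eBayes trend with robust estimation, array weights, the replicate number as a block, the mean over a gene's probes, other thresholds, other set tests and leaving out each pool. A crossed block and covariates for sex and muscle content were added after seeing the data.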

Results

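Gene expression in the sciatic nerve was compared between LKB1-SCKO mice, in which the kinase LKB1 (gene Stk11) was deleted in Schwann cells, and control mice that carried the floxed gene without Cre recombinase. The age, postnatal day 60, was chosen to precede the axon degeneration of these mutants, so the comparison asks which nerve transcripts differ before axons are lost. Each genotype had 2 arrays, each with a pool of 3 nerves from different mice. Between 19588 and 20627 probes were detected per array, 43.3% to 45.6% of those present. Across the 10858 genes tested, log2 values correlated at 0.990 between the control pools, at 0.986 between the LKB1-SCKO pools and at 0.966 to 0.977 between genotypes, where genes are not independent replicates.

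Stk11, the targeted gene, was lower in both LKB1-SCKO pools than in both control pools. Its log2 intensity was 9.70 and 9.83 in the control pools and 8.93 and 9.01 in the LKB1-SCKO pools, a log2 fold change of -0.80 (SE 0.133, limma, adjusted p = 0.0448). Unprocessed signals averaged 1024 in controls and 617 in LKB1-SCKO. Leaving out any 1 of the 4 pools kept the direction but ended the call, with adjusted p between 0.0788 and 0.217, and the call also rested on the settings given for Stk11 in the closing section. Whether the only Stk11 probe lies in the deleted part is not known, and nerve cells other than Schwann cells keep the gene.

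In LKB1-SCKO nerves 267 genes rose and 145 fell (limma, Benjamini-Hochberg), 204 of them at least 2-fold up and 94 at least 2-fold down. The gene with the largest rise was Tyrp1, an enzyme of melanin synthesis, at 12.56 and 12.26 in the LKB1-SCKO pools against 5.63 and 4.61 in controls, where 1 of 2 arrays detected it (log2 fold change 7.29, SE 0.348, adjusted p = 0.00329). Piwil4, a Piwi protein that binds small RNAs, rose by at least 4.64 on the log2 scale, Nmu, which encodes the neuropeptide neuromedin U, at least 21.5-fold, the bile acid receptor gene Nr1h4 at least 15.1-fold and the coagulation factor gene F5 at least 7.40-fold. None of these 4 was detected in a control pool. In other settings their smallest log2 fold changes were 2.70, 2.53, 2.11 and 1.48, so these bounds too hold for the main processing only. The chemokine gene Cxcl14 rose 15.2-fold, the endocytosis gene Pacsin1 14.1-fold, the small GTPase gene Diras2 12.5-fold, the LIM protein gene Csrp2 12.2-fold and Gpr137c 11.1-fold. Cpne4, a copine, and Prkg2, a cGMP-dependent kinase, rose by 3.52 and 3.38 on the log2 scale, and each was detected in 1 of 2 control pools.

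Crygs, a lens crystallin gene also present in nerve here, had the largest fall, from 9.48 and 9.23 in control pools to 5.26 and 4.80 in LKB1-SCKO pools, where 1 of 2 arrays detected it (log2 fold change -4.33, SE 0.204, adjusted p = 0.00329). Aldoc, the aldolase C gene of glycolysis, was 6.82-fold lower in LKB1-SCKO, the collagen VIII gene Col8a2 5.53-fold, Bmerb1 5.01-fold, the secretory granule gene Scg5 4.73-fold, the neurite growth gene Nrn1 4.64-fold, Slitrk5 4.51-fold and the adenylyl cyclase gene Adcy1 4.21-fold. On the log2 scale these are -2.77, -2.47, -2.32, -2.24, -2.22, -2.17 and -2.07. The smallest in other settings were -1.47, -1.64, -0.995, -1.43, -2.01, -1.30 and -1.30. Rspo1, which encodes a secreted activator of Wnt signalling, fell at least 4.80-fold, the cytochrome P450 gene Cyp2j13 at least 3.63-fold and the synaptic active zone gene Erc2 at least 3.49-fold, none of them detected in an LKB1-SCKO pool. In other settings their smallest log2 fold changes were -0.949, -0.959 and -0.838, so these bounds hold for the main processing only. Dnali1, a dynein light chain gene, fell by 2.60 on the log2 scale and was detected in 1 of 2 LKB1-SCKO pools. The adjusted p of these 24 genes lay at 0.0282 or below. Without control 1 or control 2, Slitrk5 (adjusted p = 0.0582 and 0.0751) and Adcy1 (adjusted p = 0.0591 and 0.0947) missed the threshold.

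**Figure D1:**
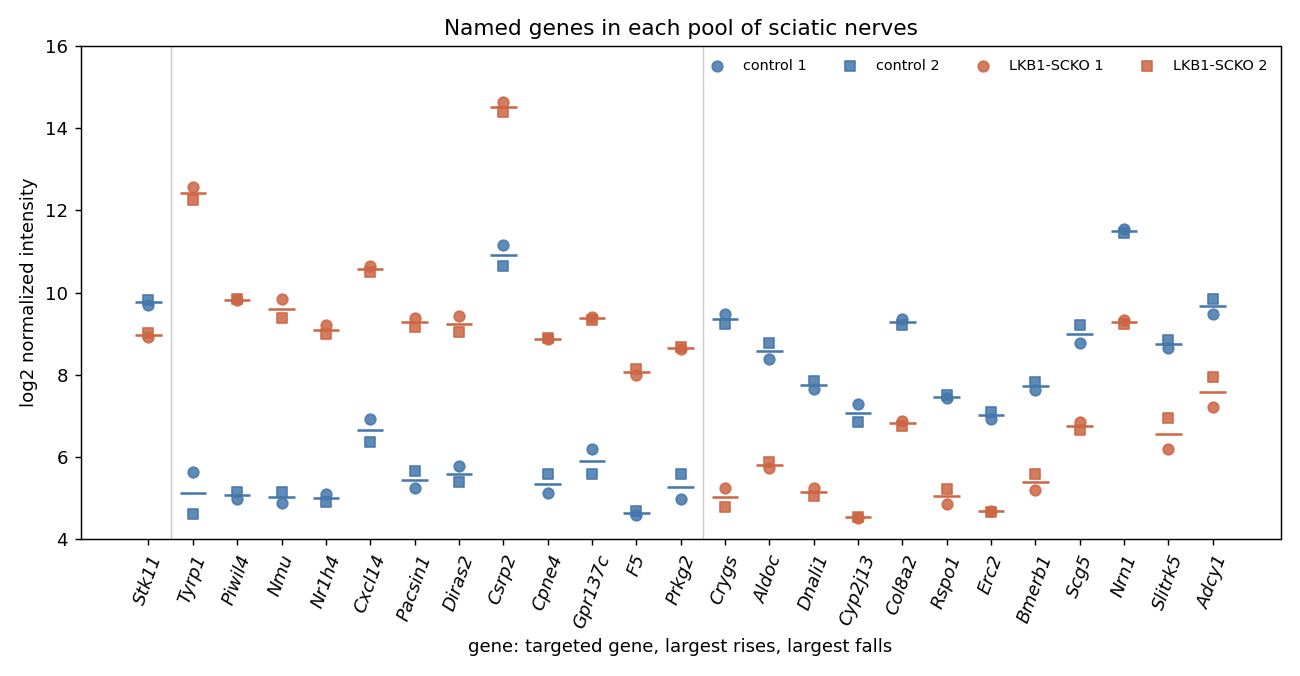
Log2 normalized intensity (vertical axis) of Stk11 and of the 12 genes with the largest rises and the 12 with the largest falls (horizontal axis) in each of the 4 pools, with a line at each genotype's mean. For every gene both LKB1-SCKO pools lie on the same side of both control pools, and Tyrp1 differs most, by 7.29.

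All 412 called genes had pools that did not overlap between genotypes, as had 55.1% of all genes tested, where chance gives 33.3%. At an unadjusted p under 0.05 there were 2429 genes. Without control 1 the count of called genes was 154, without control 2 it was 117, without LKB1-SCKO 1 it was 217 and without LKB1-SCKO 2 it was 431, so the number depended on which pool was left out. Other kept probes of called genes, 176 probes of 132 genes, had the same sign in 167 cases. Of these, 138 had an unadjusted p under 0.05 (limma). They read the same pools, so the shared sign is not independent support. Sizes could differ in either direction. Another probe stood at 0.49 for Shh (2.17 at its brightest), 0.44 for Ccl4 (1.82) and 4.73 for Cxcl14 (3.92). Other probes of Tnc stood at -0.33 and 2.28 (2.22).

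Genes of immature and repair Schwann cells moved in both directions, with more of them higher in LKB1-SCKO. Of 20 measured members, 6 rose and 1 fell, and 9 rose and 3 fell when adjusted over the list alone. Pou3f1, a transcription factor of promyelinating Schwann cells, rose 7.28-fold (log2 fold change 2.86, adjusted p = 0.00602), the growth factor gene Btc 4.91-fold, the matrix gene Tnc 4.67-fold and Shh, which encodes the morphogen sonic hedgehog, 4.50-fold. Btc, Tnc and Shh thus stood at 2.29, 2.22 and 2.17 on the log2 scale. The smallest values of these 4 genes in other settings were 2.60, 0.947, 1.39 and 1.19. Named after their values were seen, Gdnf, a neurotrophic factor gene undetected in controls, rose at least 3.11-fold, the adhesion gene Mcam rose by 1.30 (adjusted p from 0.0522 to 0.147 without each pool), and the sodium channel gene Scn7a fell by 1.79 on the log2 scale. Jun (0.79, adjusted p = 0.0738), Ngfr (0.54), Sox2 (0.32) and Gap43 (-0.41), other members, did not pass. The list passed camera (median log2 fold change 0.36, or 0.22 with undetected genes at their bound, adjusted p = 0.0413; adjusted p = 0.716 with an estimated correlation). The call was lost without control 2 (adjusted p = 0.0536) or LKB1-SCKO 1 (adjusted p = 0.176), with the stricter detection filter (adjusted p = 0.0985), with the mean over probes (adjusted p = 0.0549), and with a muscle covariate added after seeing the data (adjusted p = 0.135).

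Myelin genes were slightly lower in LKB1-SCKO as a group, while most members did not pass on their own. Drp2, a component of the dystroglycan complex of myelinating Schwann cells, fell 1.88-fold (log2 fold change -0.91, adjusted p = 0.0457), the only 1 of 20 measured members past the threshold. Adjusted over the list alone 4 fell. Camera gave an adjusted p of 0.0304 with a median of -0.27 (adjusted p = 0.716 with an estimated correlation). Mean log2 values of the list were 12.88 and 12.89 in the control pools and 12.61 and 12.67 in the LKB1-SCKO pools. Mbp, which encodes myelin basic protein, differed by -0.05 at its brightest probe, whose unprocessed signal of 63168 in control 1 was the highest on that array. Its other 4 probes gave -1.10, -0.85, -0.57 and 0.15, none past the threshold. The list's call was lost without control 1 (adjusted p = 0.0659) or control 2 (adjusted p = 0.0504) and with the muscle covariate (adjusted p = 0.0596), and the call of Drp2 was lost without control 1, control 2 or LKB1-SCKO 1 (adjusted p = 0.156, 0.192 and 0.105).

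Cholesterol synthesis genes were lower in LKB1-SCKO almost throughout, with 17 of 18 measured members below 0 and a median log2 fold change of -0.55. Sc5d, lathosterol oxidase, fell 2.22-fold, the sterol demethylation enzyme gene Msmo1 1.89-fold and the isoprenoid isomerase gene Idi1 1.81-fold (adjusted p = 0.0273, 0.033 and 0.0355). These 3 were the members past the threshold over all genes, and 12 fell when adjusted over the list alone. Camera gave an adjusted p of 2e-07 (adjusted p = 0.716 with an estimated correlation). Leaving out 1 pool did not end the list's call, but Msmo1 and Idi1 missed the threshold without any 1 of the 4 pools (adjusted p from 0.0598 to 0.179) and Sc5d without control 1, control 2 or LKB1-SCKO 1 (adjusted p = 0.103, 0.124 and 0.0647).

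Fatty acid and energy metabolism lists did not pass camera. Among 20 measured genes of glycolysis and lactate transport, Aldoc fell and Pfkp, the platelet-type phosphofructokinase gene, rose 1.96-fold (adjusted p = 0.028), the same 1 up and 1 down adjusted over the list alone, with a camera adjusted p of 0.917, a median of 0.053 and a mean of -0.09, so that these differed in sign. Pfkp missed the threshold without any 1 of the 4 pools (adjusted p from 0.0501 to 0.128). Fatty acid synthesis had 0 of 21 members past the threshold in limma (6 at an unadjusted p under 0.05, 0 adjusted over the list alone), with Fads1 at -0.44 and Scd1 at 0.30 and a camera adjusted p of 0.544. Fatty acid oxidation had 0 of 20 (2 unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.365), with Acadm at 0.10 and Etfa at 0.27. For oxidative phosphorylation the count was 0 of 61 (5 unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.862), with Atp5b at 0.15 and Atp5g3 at 0.18. The citrate cycle had 0 of 21 (0 unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.198), with Idh3g at 0.16 and Got2 at 0.33.

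Of 20 measured members of the proliferation list, made of cell cycle genes, 6 rose past the threshold in LKB1-SCKO, 0 fell and 14 did not pass, with 18 of the 20 above 0, and 13 rose and 1 fell when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, was undetected in controls and rose at least 4.22-fold, the mitotic spindle gene Nusap1 and the survivin gene Birc5 each rose 3.58-fold, and the cyclin-dependent kinase gene Cdk1 rose 2.88-fold (adjusted p = 0.028, 0.0262, 0.0141 and 0.0392). Nusap1, Birc5 and Cdk1 stood at 1.84, 1.84 and 1.53 on the log2 scale. Their smallest values in other settings were 0.82, 0.90 and 0.59. The remaining 2, named after their values were seen, were Aurkb, a mitotic kinase gene undetected in controls that rose at least 1.92-fold, and the replication licensing gene Mcm2 (2.18-fold). Camera gave an adjusted p of 1.1e-06 with a median of 0.75 (adjusted p = 0.716 with an estimated correlation). The list's call held without each pool, whereas Top2a, Nusap1 and Cdk1 missed the threshold without control 1 (adjusted p = 0.0891, 0.089 and 0.105) or control 2 (adjusted p = 0.0721, 0.0692 and 0.147), and Birc5 without control 2 (adjusted p = 0.0571). Aurkb missed it without any 1 pool (adjusted p from 0.0503 to 0.094), and Mcm2 without control 1, control 2 or LKB1-SCKO 1 (adjusted p = 0.0891, 0.172 and 0.0924).

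Macrophage genes were higher in LKB1-SCKO, with 16 of 19 measured members above 0, a median log2 fold change of 0.66 and a camera adjusted p of 0.00106 (adjusted p = 0.721 with an estimated correlation). Ms4a7, a membrane protein gene of macrophages, rose 7.11-fold, the fractalkine receptor gene Cx3cr1 3.65-fold, the pore-forming protein gene Mpeg1 2.43-fold and the lysosomal gene Laptm5 1.76-fold (adjusted p = 0.0211, 0.0287, 0.0402 and 0.0479). These were the 4 members past the threshold, and 7 rose when adjusted over the list alone. Cd163 and Mrc1, scavenger receptor and mannose receptor genes of tissue-resident macrophages that were named after their values were seen, stood at -1.25 and -0.47 and did not pass. Red blood cell genes, given with their values among the blood markers, were also higher in both LKB1-SCKO pools. The mean of the macrophage list was 8.91 and 9.53 in the control pools and 10.05 and 9.68 in the LKB1-SCKO pools, and without control 1 the list missed the threshold (adjusted p = 0.0692). Laptm5 missed it without any 1 pool (adjusted p from 0.0928 to 0.191), Mpeg1 without control 1, control 2 or LKB1-SCKO 1 (adjusted p = 0.137, 0.129 and 0.0673) and Cx3cr1 without control 2 (adjusted p = 0.0907).

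Of 21 measured members of the chemokine and cytokine list 7 rose past the threshold, 0 fell and 14 did not pass, with 14 above 0 and 7 below, and 9 rose when adjusted over the list alone. Beside Cxcl14, the metalloproteinase inhibitor gene Timp1 rose 3.65-fold, Ccl4 3.53-fold and Cxcl10, detected in 1 of 2 control pools, by 1.77 on the log2 scale (adjusted p = 0.0282, 0.0431 and 0.0429). Named after their values were seen, Ccl3 (at least 2.23-fold) and Ccl5 (at least 1.98-fold), both undetected in controls, and Cxcl13 (log2 fold change 1.08, detected in 1 of 2 control pools) made up the 7, and each missed the threshold without at least 3 of the 4 pools (highest adjusted p = 0.116, 0.181 and 0.163). Camera gave an adjusted p of 0.00259 with a median of 0.77 (adjusted p = 0.716 with an estimated correlation). The list's call held without each pool, but ended under the stricter detection filter (adjusted p = 0.116). Without control 2 or LKB1-SCKO 1 the calls of Timp1 (adjusted p = 0.074 and 0.0647), Ccl4 (0.0608 and 0.0893) and Cxcl10 (0.0726 and 0.074) were lost, as were that of Ccl4 without LKB1-SCKO 2 (adjusted p = 0.0788) and that of Cxcl10 without control 1 (adjusted p = 0.121).

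Other immune lists had no member past the threshold in limma. Interferon response genes were slightly lower, with a median of -0.13 over 19 members (3 at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.0413; adjusted p = 0.716 with an estimated correlation). Among its brightest members Irgm1 stood at -0.52 and Ifi27 at -0.07, and the list missed the threshold without control 1 (adjusted p = 0.275) or LKB1-SCKO 2 (adjusted p = 0.0893), with median scaling (adjusted p = 0.0584) and with the mean over probes (adjusted p = 0.0521). MHC class II genes had a median of -0.46 over 8 members (3 unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.0574), with H2-DMa at -0.67 and Cd74 at -0.50. Lymphocyte markers had a median of 0.62 (0.44 with undetected genes at their bound) over 6 members (3 unadjusted, 1 adjusted over the list alone; camera adjusted p = 0.0504), with Cd52 at 0.73 and Il7r at 0.38. Mast cell markers had a median of 0.34 over 7 members (1 unadjusted, 1 adjusted over the list alone; camera adjusted p = 0.0534), with Cpa3 at 0.33 and Mcpt4 at 0.24. These 3 lists lay close to the threshold and passed camera in several other settings. With an estimated correlation their adjusted p was 0.721, 0.716 and 0.716. All 3 passed with the authors' processed values (adjusted p = 0.0424 each), MHC class II and mast cell markers also without background correction (adjusted p = 0.0346 and 0.0448) or with an offset of 50 (0.0451 and 0.0453), and MHC class II with the stricter detection filter (0.0232). Lymphocyte and mast cell markers passed with median scaling (0.00754 and 0.0458) or without the detection filter (0.00918 and 0.0411), and lymphocyte markers with cyclic loess (0.0461), array weights (0.0474) or the muscle covariate (0.02). With the male-content covariate lymphocyte and mast cell markers passed (0.0348 and 0.0333). Left-out pools also moved them: MHC class II without control 1 (adjusted p = 0.00135), lymphocyte markers without control 2, LKB1-SCKO 1 or LKB1-SCKO 2 (adjusted p = 0.0206, 0.0178 and 0.00774) and mast cell markers without control 2 (adjusted p = 0.0495).

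**Figure D2:**
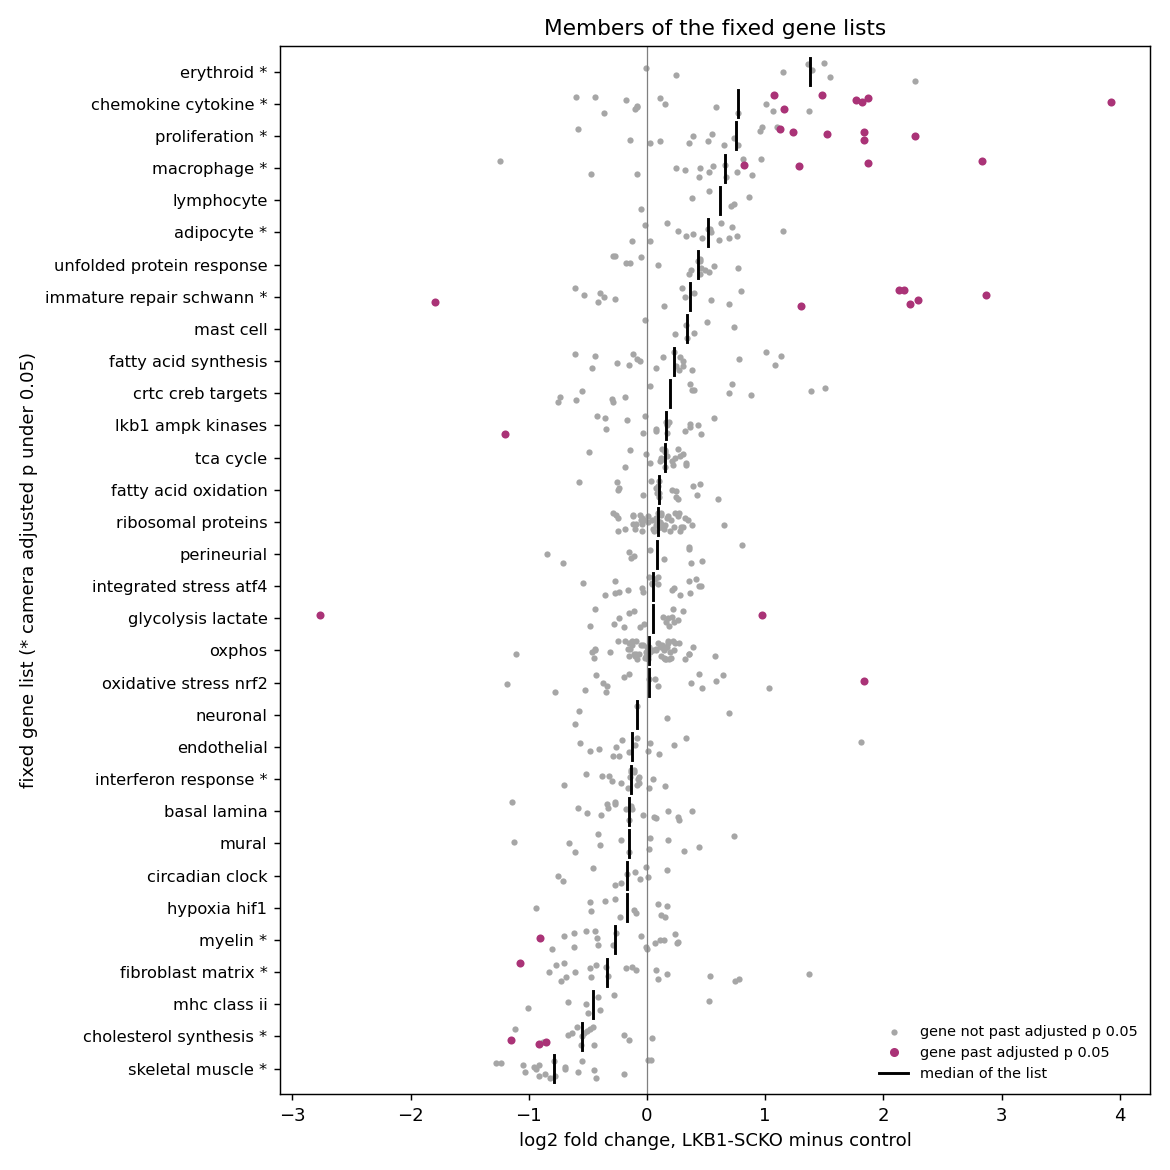
Log2 fold change of LKB1-SCKO over control (horizontal axis) for each measured member of the 32 tested lists (vertical axis), with coloured points for genes past an adjusted p of 0.05, a black line at each list's median and an asterisk where camera gave an adjusted p under 0.05. The 11 lists with an asterisk run from a median of -0.78 for skeletal muscle to 1.38 for the red blood cell list.

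Fibroblast and collagen matrix genes were lower as a group, with Lox, the collagen cross-linking enzyme gene, down 2.11-fold (adjusted p = 0.0423) as the only 1 of 22 measured members past the threshold. Adjusted over the list alone 1 rose and 5 fell. Camera gave an adjusted p of 0.0285 with a median of -0.34 (adjusted p = 0.716 with an estimated correlation). The list's call was lost without control 1, control 2 or LKB1-SCKO 2 (adjusted p = 0.0739, 0.0624 and 0.146) and with median scaling (adjusted p = 0.0584), and that of Lox without any 1 pool (adjusted p from 0.0565 to 0.146). Basal lamina (0 of 19; 5 unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.1, and 0.0489 without background correction), perineurial (0 of 12; 4 unadjusted, 0 adjusted over the list alone; 0.823), endothelial (0 of 16; 4 unadjusted, 0 adjusted over the list alone; 0.328) and mural cell lists (0 of 13; 4 unadjusted, 2 down adjusted over the list alone; 0.357) did not pass in limma or camera. Their brightest members were Itgb4 at -0.13 and Col4a1 at -0.58 for basal lamina, Itgb4 and Slc2a1 (-0.11) for perineurium, Egfl7 (-0.48) and Ramp2 (-0.41) for endothelium, and Acta2 (0.17) and Myl9 (-0.66) for mural cells. Among 5 neuronal transcripts 0 passed (3 unadjusted, 1 up adjusted over the list alone; camera adjusted p = 0.791), with Uchl1 at 0.69 and Stmn2 at -0.08.

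Skeletal muscle and fat markers differed between pools of the same genotype, and no single marker passed the threshold between genotypes. Skeletal muscle genes averaged 8.89 in LKB1-SCKO 1 and 10.59, 10.43 and 10.69 in control 1, control 2 and LKB1-SCKO 2. Camera called the list lower (median -0.78, adjusted p = 0.0217; adjusted p = 0.855 with an estimated correlation), with 0 of 21 members past the threshold in limma (1 unadjusted, 0 adjusted over the list alone), Myl1 at -0.44 and Pvalb at -0.58. Without LKB1-SCKO 2, Myl1 (-1.14, adjusted p = 0.0461) and Pvalb (-1.54, adjusted p = 0.0307) passed, and without LKB1-SCKO 1 they stood at 0.27 and 0.37. Without LKB1-SCKO 1 the list turned up (median 0.20, adjusted p = 0.176), and it missed the threshold without control 1 (adjusted p = 0.0659). Adipocyte genes averaged 8.55 in control 2 against 9.55 in control 1, and 9.68 and 9.32 in the LKB1-SCKO pools. That list was called higher (median 0.52, adjusted p = 0.0413; adjusted p = 0.857 with an estimated correlation) with 0 of 17 members past the threshold in limma (1 unadjusted, 0 adjusted over the list alone), Lpl at 0.39 and Pnpla2 at 0.33. Without control 2 camera's direction turned down (adjusted p = 0.988), and without LKB1-SCKO 1 the call was lost (adjusted p = 0.381). It was also lost with the mean over probes (adjusted p = 0.0521) and with covariates for male content (adjusted p = 0.0647) or muscle (adjusted p = 0.183), both added after seeing the data.

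Red blood cell genes were higher in both LKB1-SCKO pools, at a mean of 9.98 and 10.95 against 9.42 and 9.15 in the control pools. The list passed camera (median 1.38, adjusted p = 0.00474; adjusted p = 0.721 with an estimated correlation), while 0 of 8 members passed limma over all genes (5 unadjusted, 4 up adjusted over the list alone). The beta-globin genes Hbb-bt and Hbb-bs stood at 1.36 and 1.54 (adjusted p = 0.0543 and 0.0872), and both passed without LKB1-SCKO 1 (log2 fold change 1.73 and 2.05, adjusted p = 0.0166 and 0.0258).

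The pools also differed in sex-linked transcripts. Eif2s3y, a Y-chromosome gene, stood at 9.54 in control 1, 8.63 in LKB1-SCKO 1 and 9.47 in LKB1-SCKO 2, and was undetected in control 2 (4.73). Xist, the transcript of the inactive X chromosome, was detected only in control 2 (10.68) and LKB1-SCKO 1 (8.82) at its brightest probe. Kdm5d, also on the Y chromosome, followed Eif2s3y, with 6.39, 4.49, 5.95 and 6.26 in control 1, control 2, LKB1-SCKO 1 and LKB1-SCKO 2. Neither Eif2s3y (log2 fold change 1.92, adjusted p = 0.5) nor Kdm5d (0.66, adjusted p = 0.561) differed between genotypes beyond the spread of the pools, although without control 1 Eif2s3y did (4.32, adjusted p = 0.0169) and without control 2 it stood at -0.49, and with 2 measured members (0 adjusted over the list alone) the list was not tested by camera.

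**Figure D3:**
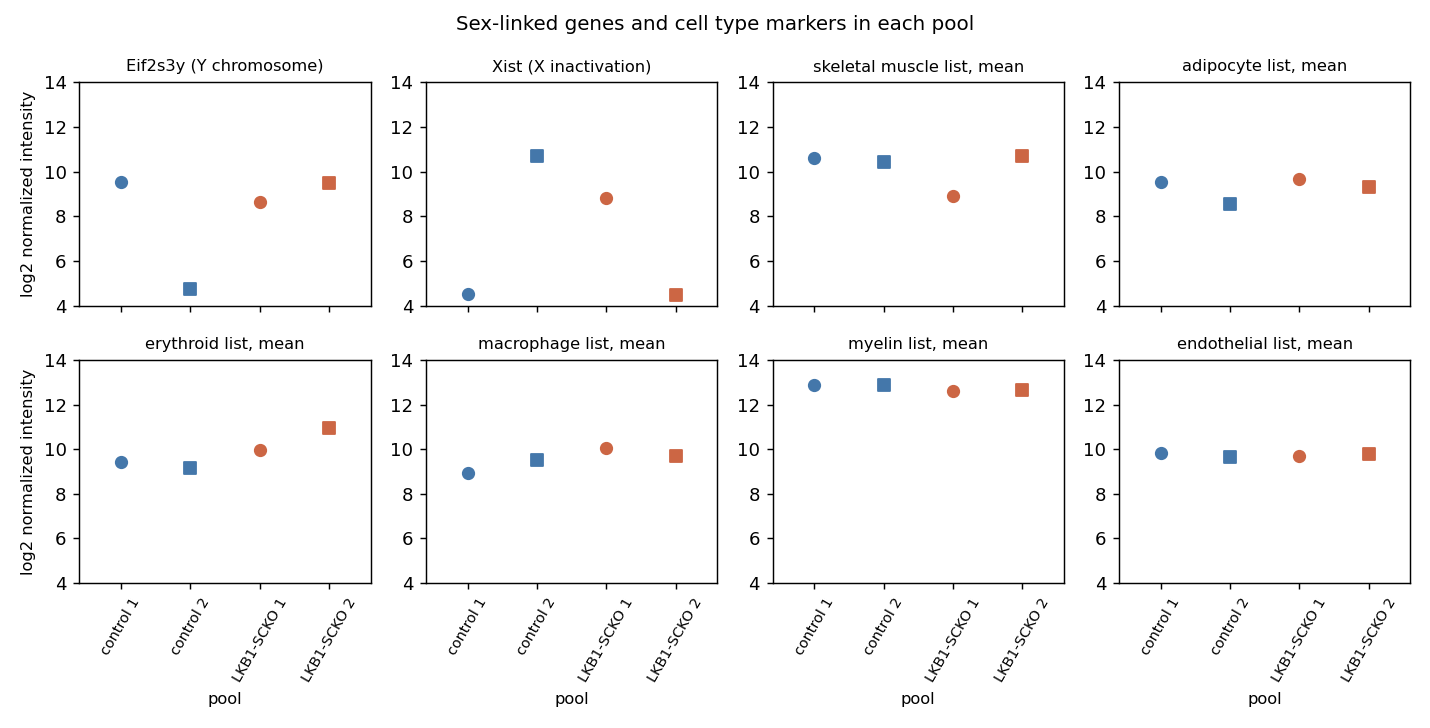
Log2 normalized intensity (vertical axes) of Eif2s3y, Xist and the mean of 6 gene lists in each of the 4 pools (horizontal axes). Control 2 lacks Eif2s3y, LKB1-SCKO 1 has both sex-linked genes and the lowest muscle mean (8.89), and red blood cell genes are highest in LKB1-SCKO 2 (10.95).

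Among the kinases related to LKB1, Prkab2, which encodes a beta subunit of AMPK, fell 2.30-fold (log2 fold change -1.20, adjusted p = 0.0158). It was the only 1 of 20 measured members past the threshold, also adjusted over the list alone, and the list did not shift (camera adjusted p = 0.791). Prkab2 missed the threshold without control 1 or control 2 (adjusted p = 0.0613 and 0.0916), and without LKB1-SCKO 1 (adjusted p = 0.05). NRF2 targets had 1 of 19 members past the threshold, the glutathione transferase gene Gsta1, which was undetected in controls and rose at least 2.75-fold (adjusted p = 0.00819). Adjusted over the list alone 2 rose and 1 fell, with a camera adjusted p of 0.843.

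The remaining lists had 0 members past the threshold in limma and did not pass camera. CREB and CRTC targets (16 members; 5 unadjusted, 3 up and 1 down adjusted over the list alone; camera adjusted p = 0.544) included Egr1 at 0.72 (0.018 to 1.41 without each pool) and Dusp1 at -0.73 (-1.28 to -0.19), and the list passed without LKB1-SCKO 2 (adjusted p = 0.0445). ATF4 targets (22 members; 4 unadjusted, 0 adjusted over the list alone; 0.606) included Gars at 0.35 and Ddit4 at -0.27, and unfolded protein response genes (17 members; 7 unadjusted, 0 adjusted over the list alone; 0.0534) included Hsp90b1 at 0.09 and Xbp1 at 0.37, and the latter list passed without control 2 (adjusted p = 0.0495) or LKB1-SCKO 2 (adjusted p = 0.00774) and with the male-content covariate (adjusted p = 0.0341). HIF1 targets (12 members; 3 unadjusted, 0 adjusted over the list alone; 0.198) had Ndrg1 at -0.36 and Slc2a1 at -0.11, and ribosomal protein genes (50 members; 1 unadjusted, 0 adjusted over the list alone; 0.248) had Rplp1 at 0.11 and Rpl41 at 0.07. Clock genes (11 members; 0 unadjusted, 0 adjusted over the list alone; 0.205) ranged from Per1 at -0.75 and Nr1d1 at -0.71 through Nr1d2 (-0.46), Arntl (-0.27), Per2 (-0.22), Dbp (-0.17), Ciart (-0.10), Clock (-0.06) and Cry2 (-0.0043) to Tef (0.0099) and Per3 (0.17). Without LKB1-SCKO 2, Nr1d1 passed (-1.35, adjusted p = 0.0362).

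In all, 11 of the 32 lists passed camera with the preset correlation, 6 higher and 5 lower in LKB1-SCKO, and 15 had an unadjusted p under 0.05. With an estimated correlation 0 passed (lowest adjusted p = 0.716, 0 at an unadjusted p under 0.05), and with fry 0 passed (lowest adjusted p = 0.224, 5 at an unadjusted p under 0.05). In fry's test for change in either direction 14 lists passed. Some of them had not passed camera: glycolysis with lactate transport (adjusted p = 0.0206), NRF2 targets (0.0026), kinases related to LKB1 (0.0206) and CREB and CRTC targets (0.0487). Basal lamina (0.0193), mural cell (0.028) and neuronal lists (0.0342) were such lists too. The interferon, adipocyte, skeletal muscle and red blood cell lists passed camera but not this test.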

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

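The splits of the pools and the tests of blood and of the Schwann cell share were chosen after the results were seen, and the fits with sex and muscle covariates were added after seeing the data, though what these fits and the test of neighbouring genes had to show was written before their own results were seen. Probes that the platform annotation leaves unnamed lay outside the gene comparisons, and 52 of 2911 such probes were higher in LKB1-SCKO and 31 lower (limma, Benjamini-Hochberg). The rise with the smallest adjusted p was at least 24.7-fold (adjusted p = 0.0005), at a probe undetected in both control pools, and the fall with the smallest was at least 5.80-fold (adjusted p = 0.0024), at a probe undetected in both LKB1-SCKO pools.

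The difference between genotypes as a whole, 412 called genes, was weighed against the makeup of the pools. There are 3 ways to split the 4 pools into equal groups, too few for a share under 0.05, and the real split gave 412 genes and the highest other 0. With a covariate for male content, the log2 fold changes of the called genes kept a median of 0.998 of their size (quartiles 0.978 and 1.02). Of the 412 calls 401 held. A gene was called only if its pools differed little within a genotype, and the slope of the covariate rests largely on those differences. A ratio near 1 was thus largely set in advance, and a different sex mix of the pools stays open. With the muscle covariate the median was 0.978 (quartiles 0.928 and 1.02), under the same limit, but 206 of the 412 calls ended. For those the median size went from 0.97 to 0.96 and the median SE from 0.143 to 0.158. Without LKB1-SCKO 1, the pool low in muscle, 411 of the 412 kept their direction. The called genes had pools that did not overlap between genotypes, so this was set by their selection, apart from the repeated normalization. Muscle content stays open too. A chromosome segment that came with the Cre line may still account for short runs, since the test covered runs of 25 neighbouring genes, where the highest number of calls was 5 and the 95th percentile of 10000 random placements was 7 (permutation test, p = 0.961), and loss of LKB1 in Schwann cells stays open as the biological explanation.

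The higher macrophage and chemokine genes were weighed against blood and against a lower share of Schwann cell RNA. More blood in the LKB1-SCKO pools was argued against as the whole cause, by 1 difference between 2 pools. The 6 haemoglobin and other red blood cell genes were higher in LKB1-SCKO 2 than in LKB1-SCKO 1 by 1.19 (SE 0.173). All 40 measured macrophage and chemokine genes differed by -0.22 (SE 0.0804, genes not being independent replicates), the macrophage genes by -0.36 and the chemokine genes by -0.09. From control 1 to control 2 the macrophage genes differed by 0.62, the chemokine genes by -0.20 and the red blood cell genes by -0.42 (SE 0.350). Macrophage genes thus varied by more than 0.22 between pools of a genotype. A lower share of Schwann cell RNA as the whole cause would raise markers of every other cell type alike, but the mean log2 fold change was 0.65 over 19 macrophage genes and 0.16 over 105 genes of 9 other lists, skeletal muscle left aside, a difference of 0.49 (permutation test over genes, p = 0.004, genes not being independent replicates). The test shuffled genes, so its p holds no spread between pools, and no chemokine gene entered it. The macrophage mean differed by 0.62 between the control pools alone. The means of the 9 other lists ran from -0.19 for fibroblasts, -0.14 for mural, -0.08 for neuronal, -0.02 for endothelial and 0.05 for perineurial cells to 0.36 for mast cells, 0.45 for adipocytes, 0.53 for lymphocytes and 1.18 for red blood cells. Mast cells and lymphocytes did not pass camera and adipocytes turned down without control 2, so a lower share as a part of the cause stays open. More macrophages in the nerve and more of these transcripts per macrophage also stay open and were not tested, and the resident macrophage genes Cd163 (-1.25) and Mrc1 (-0.47) lay in the other direction without passing the threshold.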

How the results depend on the processing

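The crossed block and the covariates for male content and muscle were added after seeing the data. Slide as a block was not run, because the sources used here give no slide. Leaving out a pool left an arm with 1 pool, which was assumed to vary like the other genotype. Precision was limited by 2 pools per genotype and, for dim probes, by signal over background. All 412 called genes kept their direction in every setting that tested them, except 1 gene each without LKB1-SCKO 1 and without LKB1-SCKO 2. The stricter filter tested 296 of them. Their pools did not overlap between genotypes in the main fit, and every setting drew on the same arrays. Their direction, also that of the called named genes counted next, was thus largely set by the selection. Stk11, which lost its call in several settings given below, is left out of the counts that follow. Among the other 47 named genes past the threshold 27 passed in every setting. Of their 825 comparisons 724 kept the call, 101 lost it and 0 reversed. Of 951 comparisons for named genes not past the threshold 874 stayed, 39 passed and 38 changed sign. Lists on cholesterol synthesis, proliferation and red blood cells were called in 18 of 20 settings. The size of change depended on the background step. Over the called genes the median ratio of log2 fold change to the main fit was 0.594 without background correction. It was 0.811 with the authors' processed values and 0.843 with an offset of 50.

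The number of called genes was 636 without background correction, 812 with an eBayes trend and robust estimation, 931 at an adjusted p under 0.1, 241 with the muscle covariate, and 117 to 431 without each pool. Apart from these and the replicate block, it stayed within 1.5 times the 412. The looser threshold passes more genes by construction, the calls that ended with the muscle covariate had a larger median SE there (0.158 against 0.143), and otherwise the cause was not tested. The number of called lists was 0 with an estimated correlation and 0 with fry, and 7 to 12 without each pool. Estimated correlations lay far above the preset 0.01 for adipocytes (0.86), red blood cells (0.77), macrophages (0.66), skeletal muscle (0.60) and cholesterol synthesis (0.46). They lay near it for chemokines and cytokines (0.020) and below it for myelin (-0.0041), lists that also lost their calls. A correlation above the preset was thus not the whole cause. With an estimated correlation the test draws on the 2 residual degrees of freedom of the fit. How far that alone raised the p-values was not tested, nor was any other cause.

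Whether pools with the same number were paired, by litter or day, is not given in the sources used here, and they were treated as unpaired. Their deviations from the group means correlated at -0.17 over genes, which cannot settle this with 2 pools per genotype. With the replicate number as a block, 172 genes were called and Stk11 stood at -0.80 (adjusted p = 0.109). With the numbers crossed, 310 genes were called, with Stk11 at -0.80, and 13 lists, 10 of them among the 11, without the immature or repair Schwann cell list.

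Stk11 missed the threshold at -0.89 with median scaling (adjusted p = 0.0548), at -0.80 without the detection filter (0.0583, where more genes were tested), at -0.80 with crossed numbers (0.0695), at -0.77 with the muscle covariate (0.0958) and at -0.87 to -0.73 without each pool (0.0788 to 0.217). Apart from the larger number of genes, the cause was not tested.

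Genes that had not passed changed sign in some settings, and the cause was not tested. With median scaling Hsp90b1 stood at -0.016, Tef at -0.080 and Rpl41 at -0.031, with cyclic loess Cry2 at 0.0045, and with the mean over probes Per3 at -0.28. With the male-content covariate Ddit4 stood at 0.19, Tef at -0.013 and Cry2 at 0.027, and with the muscle covariate Arntl at 0.0081, Myl1 at 0.13 and Pvalb at 0.18. Without each pool the ranges were -0.070 to 0.28 for Acadm, -0.013 to 0.33 for Idh3g, -1.23 to 0.70 for Ddit4, -0.0025 to 0.19 for Hsp90b1, -0.23 to 0.00033 for Slc2a1, -0.63 to 0.082 for Arntl, -0.16 to 0.045 for Clock, -0.85 to 0.42 for Per2, -0.016 to 0.35 for Per3, -0.071 to 0.091 for Tef, -0.25 to 0.13 for Ciart and -0.075 to 0.065 for Cry2. They were -0.0099 to 0.79 for Il7r, -0.20 to 0.058 for Ifi27, -0.021 to 0.80 for Lpl, -1.14 to 0.27 for Myl1, -1.54 to 0.37 for Pvalb, -0.28 to 0.0091 for Itgb4, -0.12 to 0.46 for Acta2, -0.49 to 4.32 for Eif2s3y and -0.28 to 1.61 for Kdm5d.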

Other observations

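The genes and lists of this part, and the test of pigment cells, were chosen after the results were seen. The first 8 genes were picked one by one among those called higher in LKB1-SCKO (limma, Benjamini-Hochberg), with no list behind them, so they say nothing about a class of genes. Ccnd1, which encodes cyclin D1, rose 3.45-fold (log2 fold change 1.79, SE 0.208, adjusted p = 0.0186), and the cyclin-dependent kinase inhibitor gene Cdkn1c rose 3.95-fold (adjusted p = 0.00478). Sox4 rose 5.43-fold, Id2, which encodes an inhibitor of helix-loop-helix transcription factors, 4.69-fold, the cadherin gene Cdh6 5.48-fold, and Tfap2a, a transcription factor of neural crest cells that was undetected in controls, at least 2.61-fold, each called without any 1 pool. Other probes of Id2 stood at 1.97 and 0.64, against 2.23 at its brightest, and another of Tfap2a at 0.49, against 1.67. Uhrf1 rose 3.43-fold and missed the threshold without control 1 (adjusted p = 0.0542), and E2f1 rose 2.08-fold but missed it without any 1 pool (adjusted p from 0.0513 to 0.141).

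Among 35 measured replication-dependent histone genes 9 rose, 0 fell and 23 stood above 0 (median log2 fold change 0.55), and the family was picked because called members had been seen, so no test of it as a group is given. H2ac7 and H2ac24 rose 3.91-fold and 3.73-fold, while the measured H2bc genes all stood below 0, and probes of these near-identical genes can bind several members. Among 11 measured genes known from microglia, 4 rose: Trem2 4.11-fold, Cx3cr1 3.65-fold, P2ry13 2.98-fold and Tmem119 2.27-fold, with 9 above 0 (median 0.93), in a list that was likewise picked after called members had been seen. Cx3cr1 and Csf1r are also in the macrophage list. Trem2 was called without any 1 pool, Cx3cr1 missed the threshold without control 2 (adjusted p = 0.0907), P2ry13 without control 2, LKB1-SCKO 1 or LKB1-SCKO 2 (adjusted p = 0.074, 0.0852 and 0.0572) and Tmem119 without any 1 pool (adjusted p from 0.0503 to 0.119).

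Of 15 pigment cell genes 8 were measured, and 4 of these were called higher in LKB1-SCKO: Tyrp1 (7.29), Pmel (2.47), Dct (2.42) and Ednrb (2.31). Tyrp1, Pmel and Dct were detected in 1 of 2 control pools, and Ednrb in both, at a mean of 9.94. Dct missed the threshold without control 2. The family was picked because called members had been seen, so no test of it as a group is given. Melanocytes in the LKB1-SCKO pools may be the source. Of 4 other melanocyte genes measured 3 were higher at an unadjusted p under 0.05 in limma: Oca2 (0.85), Mitf (0.51) and Rab38 (0.32). Over all genes 2429 of 10858 reached that level. These 3 did not pass after adjustment (adjusted p from 0.0562 to 0.219), and Mlph stood at -0.08. Oca2 was measured only through its detection in the LKB1-SCKO pools, and the remaining 7 of 11, among them Tyr and Mlana, were not detected on both arrays of a genotype. The rule for melanocytes as the source asked for more rising genes than were measured, so the count could not decide and left this open. A change of these genes in Schwann cells, which also come from the neural crest, stays open and untested. Next to Tyrp1 in gene order, Lurap1l (2.07, adjusted p = 0.0251) and Mpdz (-0.97, adjusted p = 0.027) also differed, Lurap1l not without control 1 or control 2 (adjusted p = 0.0802 and 0.0721) and Mpdz not without any 1 pool (adjusted p from 0.0545 to 0.143), and a short segment of another strain there was not excluded. The run of 25 neighbouring genes that holds Tyrp1, Lurap1l and Mpdz had 5 calls in all, the others being Tnc (2.22, adjusted p = 0.00656), which stayed called whichever pool was left out, and Tmem268 (1.21, adjusted p = 0.0391), which then missed the threshold each time (adjusted p from 0.0527 to 0.138).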
